A study of Marchantia polymorpha with 12 samples.

How the data were processed

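Libraries were made, per the labels' protocols, from polyadenylated RNA of 14-day thalli with a directional kit, and 12 libraries were used, 3 in each of 4 groups. Per the labels, each of 2 experimental sets held its own Mpknox2-1 controls and 1 of 2 double mutants, and replicates are biological. The deposited tables give raw counts per gene and per TE copy, 2 tables for each library, 24 in all. Reads were trimmed with Trim Galore and aligned with STAR, per the submitters' processing notes, which carry no versions. The aligner settings, the counting tool, its treatment of reads that fit several places, and the genome build are not given in the sources used here. The second table of each library was taken as the opposite strand because its gene counts were 1.66% to 2.17% of all gene counts; that reading comes from the gene values and the file naming. TE counts were higher in the second tables, 366632 to 1028910 per library, and the strand taken for TE copies is not given.

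Each table held 19441 genes and 89262 TE copies. Gene counts summed to between 7019900 and 12098548 per library, TE counts of the first tables to between 29645 and 85937, and antisense gene counts to between 126357 and 225298. Gene symbols came from a reference table of assembly MpTak2 version 7.1 by identifier number: 17624 identifiers matched, and 3088 of these had a symbol. The files name no build, so only names and neighbouring genes were taken from that table, and it holds neither products nor strand. No pair of replicates was a repeated library: chi-square per degree of freedom between replicates was 2.76 to 32.4.

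Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit robust, glmQLFTest), after filterByExpr with a minimum count of 10 and a minimum total of 15, TMM scaling over genes and TE copies together, and Benjamini-Hochberg adjustment within genes and within TE copies. The threshold was an adjusted p of 0.05. Each double mutant was compared with the controls of its own set in a fit of 6 libraries. The mean over sets and the difference between sets (set 2 minus set 1) came from a fit of all 12. That fit shares a single dispersion per gene between the sets. Replicate noise was unequal, with chi-square per degree of freedom of 6.81 to 32.4 in set 1 and 2.76 to 11.2 in set 2. In the fit of all 12, 7486 genes passed in set 1 and 4082 in set 2, against 6395 and 4815 in the fits of 6. TE families are sums over copies; antisense tables used the library sizes and factors of the first tables. CPM values are means ± SD of 3 libraries. The SE of a log2 fold change is its absolute value divided by the square root of the edgeR F statistic. It is thus derived from the test and is no separate measure of precision. Where a group had 0 counts, a fold was bounded against a floor of 3 counts summed over its 3 libraries. With 1 to 3 counts, the pooled ratio is given with an exact 95% interval. Floors cover the counting error of the group with 0 counts only, and intervals the counting error of both groups only. At these depths a gene with 0 counts in a group can still be transcribed below that floor.

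The tests, samples, thresholds and rule for named genes were fixed before the data were examined. The rule took the targeted genes, the 10 genes in each direction with the largest smaller fold change of both sets and a mean CPM of at least 1, up to 3 called genes per list, the 4 genes with the smallest adjusted p for the difference, and TE families, TE copies and antisense genes by like criteria. It was written for product names, and symbols were used in their place since the reference holds none. MpE(z)2, MpE(z)3, MpVg01240, TE_00000630 and the families and runs of neighbouring genes named in the closing part were chosen after their values were seen.

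The 24 gene lists fixed before the data were examined rested on product names and could not be applied, except the V chromosome list. For them 29 lists on symbols were written after some raw counts had been seen and before any fit. The plan had been to test chromosome and TE lists alone if products were missing, so the symbol lists are an addition to it. Photosystem and ribosomal protein lists had no counterpart among the symbols. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 28 lists with at least 5 tested members. The share of risen genes in symbol families was compared after the calls were known.

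The procedure was tested on 10 simulated data sets per comparison, each with 200 genes changed by a known fold. The number of data sets was raised from 1 to 10 after the first had been seen. Changed genes were drawn from those with an average above 1 CPM, as many raised as lowered. Recovery of rarer or silent genes was thus not simulated. Simulations of the mean and the difference used the dispersion shared by both sets, so they cannot show what unequal noise of the sets does. Far fewer genes changed than were called in the real libraries, so the shares below hold for the simulated setting. With a 4-fold change 92.5% of genes were recovered in set 1, 97% in set 2, 97.9% for the mean over sets and 85.1% for the difference. With a 2-fold change these were 71%, 83.5%, 86.9% and 59.2%. False calls were 7.93%, 6.73%, 5.40% and 5.00% of all calls.

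Alternatives tried were DESeq2 1.42.0, RLE scaling, no filter, scaling from genes only, all 12 libraries in 1 fit, the antisense tables' own scaling, the replicate number as a block, a threshold of 1 log2 unit and each library left out in turn. Added after the data had been seen were fits without MpVg01240 and 3 abundant TE families, and fits without the 2 set 1 libraries with the most MpVg01240 counts. Closing tests were also altered after their first results. The count of antisense genes that rose without a called rise on the sense strand was narrowed to those above a strand leak bound, and both counts are given. The test of genotype behind abundant features first asked for a difference between the groups, with a smallest exact p of 0.5, and was replaced by deviations from group means, first over all 12 libraries (lowest r 0.927) and then in set 2 for families ranked on set 1 alone. The first form left the genotype open and the later ones went against it as the whole origin. The test of dilution first asked whether the 138 genes called with a larger rise in set 2, against 1039 with a smaller one, exceeded 5% of all genes risen on average. They did not, so that test left dilution open. It was replaced by their share of called differences, adjusted first over all genes and then over the risen genes alone, and both of these went against dilution as the whole origin. A breakdown of risen genes by their control level was made and left out, because genes with low control counts pass the filter only through high counts in the mutants.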

Results

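RNA was measured in 14-day thalli of the liverwort Marchantia polymorpha, the flat haploid body of the plant, by strand-specific sequencing of polyadenylated RNA. Each of 2 experimental sets held 3 libraries of the Mpknox2-1 single mutant and 3 of a double mutant, 12 libraries in all. The double mutant carried Mpez1-1 in set 1 and Mpez1-2 in set 2. The comparisons therefore addressed what a mutation of MpE(z)1, in an Mpknox2-1 background, did to transcripts of genes and transposable elements (TEs), and whether both alleles gave like results. Gene counts per library ranged from 7019900 to 12098548. In the first of 2 tables per library TE copies took 0.293% to 1.00% of the counts. The second table, read as the opposite strand, held 1.66% to 2.17% of all gene counts, while its TE counts, 366632 to 1028910 per library, exceeded the 29645 to 85937 of the first. No library of plants without the Mpknox2-1 mutation was analysed here.

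The targeted genes were examined first. MpE(z)1 (MpCXC3, Mp5g18040) encodes an Enhancer of zeste homologue, the catalytic subunit of the Polycomb repressive complex PRC2, which methylates histone H3 at lysine K27. Its counts were 360, 304 and 248 in the set 1 controls and 120, 123 and 80 in the Mpez1-1 libraries. In CPM (counts scaled to the size of each library) it went from 27.5 ± 3.89 to 13.2 ± 1.75 (SD, n = 3 libraries each), a log2 fold change of -1.06 (SE 0.15, edgeR adjusted p = 0.000607). In set 2 the counts were 392, 344 and 416 in the controls and 165, 217 and 204 in the Mpez1-2 libraries, or 37.8 ± 3.16 and 22.0 ± 1.76 CPM (log2 fold change -0.78, SE 0.10, edgeR adjusted p = 3.36e-05). MpE(z)1 transcripts were thus lower in all double mutant libraries and were not lost in any. MpKNOX2 (MpHD21, Mp7g05320), a homeodomain transcription factor gene mutated in all 12 libraries, had counts of 0, 0 and 2 in the set 1 controls and 9, 6 and 15 in the Mpez1-1 libraries. The pooled ratio was 20.4, with a 95% counting interval of 5.17 to 176. In set 2 it had 0 counts in the 3 controls and 3, 8 and 4 in the Mpez1-2 libraries. That was 5.74-fold higher against the floor, with a lower 95% counting limit of 4.12. MpKNOX2 was too low to be tested in either set. Of the related genes, MpE(z)2 (Mp5g17740) rose from 0 counts in the controls of both sets, at least 35.3-fold in set 1 and at least 26.0-fold in set 2. MpE(z)3 (Mp5g22900) had 1 count in the set 1 controls, 2 in the Mpez1-1 libraries and 0 in set 2.

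**Figure D1:**
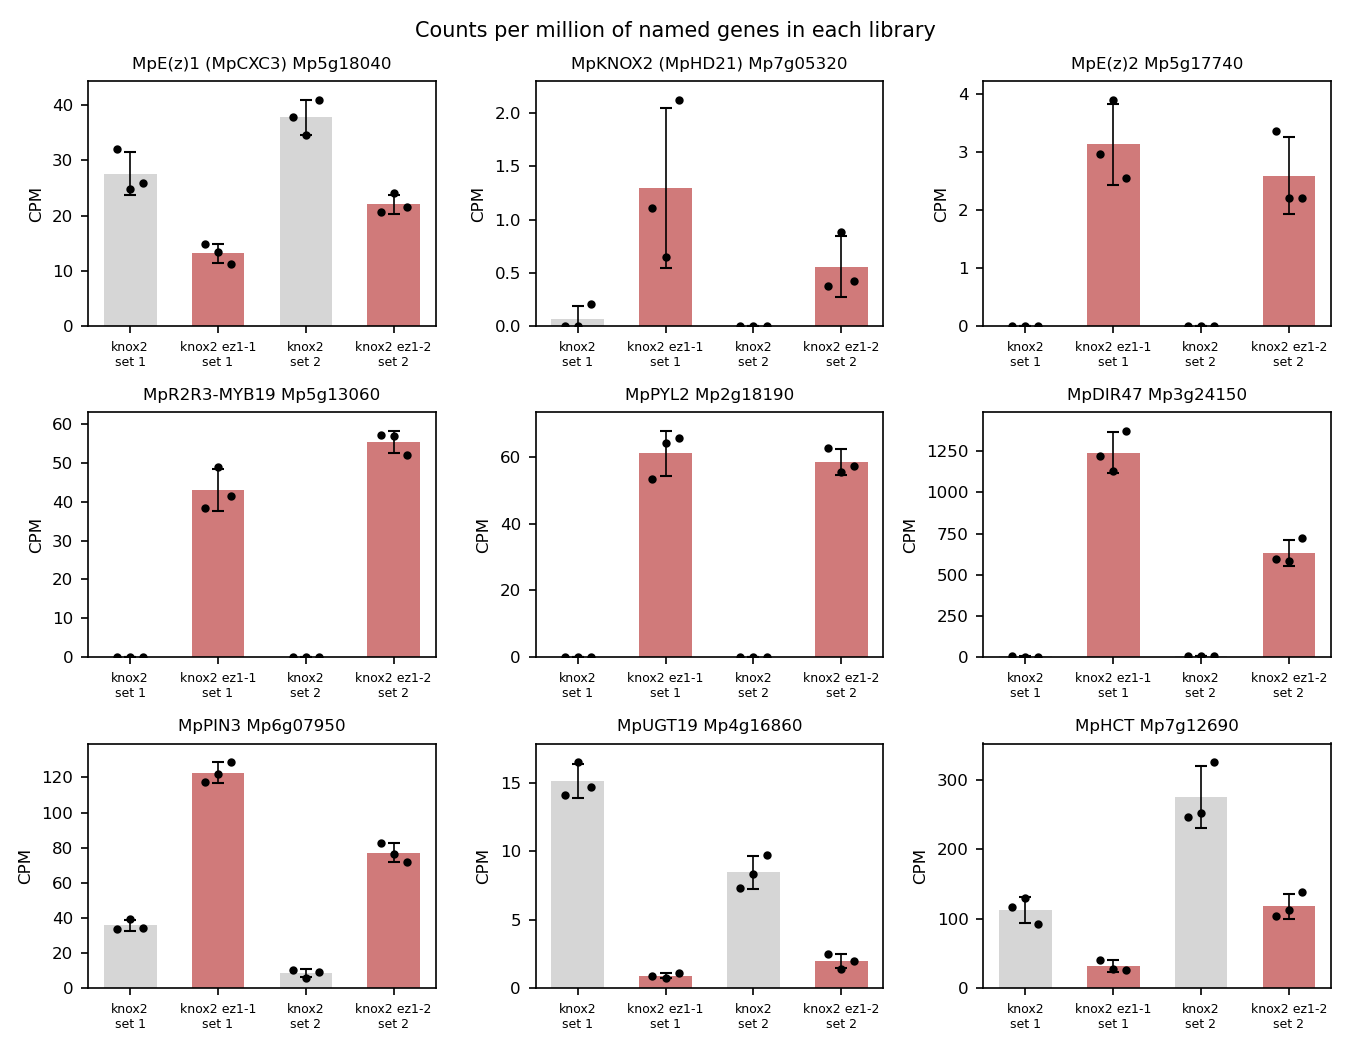
CPM of 9 genes in each of the 12 libraries, by group; bars are means of 3 libraries, error bars SD and points single libraries. MpE(z)1 was lower in each double mutant group than in its controls (27.5 against 13.2 CPM in set 1), MpR2R3-MYB19 and MpE(z)2 had 0 counts in the controls, and MpUGT19 and MpHCT were lower in both double mutants.

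In set 1, most genes named for the largest rises in the Mpknox2-1 Mpez1-1 thalli were silent or nearly silent in the controls. That is in part built in, since such genes pass the filter only through high counts in the double mutants. MpR2R3-MYB19 (Mp5g13060), a MYB transcription factor gene, went from 0 counts to 42.9 ± 5.43 CPM, at least 478-fold higher. MpPR1g (Mp2g15990), of the pathogenesis-related PR1 family, rose from 0 counts to 28.7 ± 4.66 CPM, at least 316-fold. MpPYL2 (Mp2g18190), of the family of abscisic acid receptors, went from 2 counts to 1487, a pooled ratio of 1010 with a counting interval of 279 to 8347. Dirigent genes, whose products guide the coupling of phenolic radicals, were among the most abundant of the risen genes: MpDIR47 (Mp3g24150) went from 6.30 ± 3.94 to 1240 ± 125 CPM (log2 fold change 7.61, SE 0.42).

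Other genes that rose in set 1 from 0 counts were MpCYP716-like24, a cytochrome P450 gene (at least 169-fold), MpPR15f of a germin-like family (at least 197-fold), MpBHLH25 (at least 53.0-fold), Mp3R-MYB6 (at least 50.3-fold), the terpene synthase gene MpTPS6 (at least 41.7-fold) and MpRING1B3, named for a subunit of Polycomb repressive complex PRC1 (at least 55.2-fold). MpBZR3, of the transcription factor family that acts in brassinosteroid signalling in flowering plants, went from 2 to 723 counts, a pooled ratio of 491 with an interval of 135 to 4062. The genes that fell included MpUGT19, a glycosyltransferase gene, from 15.1 ± 1.26 to 0.919 ± 0.192 CPM (log2 fold change -4.04, SE 0.21, edgeR adjusted p = 5.37e-06). The polyphenol oxidase gene MpPPO6 changed by -3.83, the peroxidase genes MpPOD4 and MpPOD25 by -2.59 and -3.14, and the expansin gene MpExpansin11 by -2.61 on the log2 scale. MpHCT, named for the hydroxycinnamoyl transferase of phenylpropanoid synthesis, fell from 113 ± 18.8 to 31.7 ± 8.43 CPM. MpGDPD, a glycerophosphodiester phosphodiesterase gene, changed by -1.49, MpCYP814-like by -1.96 and the pectin methylesterase-type gene MpCE8.14 by -0.98. The call for MpCE8.14 was lost, at -0.86, without control replicate 2. MpPOD94 went from 45 counts to 3, a pooled ratio of 0.0906 with an interval of 0.0180 to 0.282.

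Of 12633 genes tested in set 1, 6395 passed at an edgeR adjusted p under 0.05, of which 3350 rose and 3045 fell; 1915 rose and 711 fell by at least 1 log2 unit. Among genes with 0 counts in all 3 controls, 98 had at least 10 counts in each of the 3 double mutant libraries, against 2 genes in the reverse direction. On simulated counts with the means of this set, a mean of 7.93% of calls were false over 10 simulations, above the nominal 5%.

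Of 28 tested gene lists defined by symbol, 7 rose in set 1 by camera with the preset correlation. Among dirigent genes, 35 of 50 tested members rose, 5 fell and 10 did not pass (36 and 5 adjusted over the list alone), with MpDIR45 at 7.86 and MpDIR64 at 7.23 on the log2 scale (camera adjusted p = 1.43e-07; adjusted p = 0.155 with an estimated correlation). Late embryogenesis abundant protein and oleosin genes, typical of spores and drying tissue, rose in 46 of 65 cases and fell in 6 (49 and 6 adjusted over the list alone), with the dehydrin gene MpDHN2 at 1.42 (camera adjusted p = 1.53e-06; adjusted p = 0.515 with an estimated correlation). Of 63 phenylpropanoid and flavonoid enzyme genes, 38 rose and 6 fell (40 and 8 adjusted over the list alone), among them MpDFR-like1 at 3.30 and MpPAL10, of the phenylalanine ammonia-lyase family, from 81.0 to 174 CPM (camera adjusted p = 3.89e-05; adjusted p = 0.163 with an estimated correlation). Terpene synthase genes rose in 17 of 22 cases and fell in 2 (17 and 2 adjusted over the list alone), with MpFTPSL3 at 5.30 and MpMTPSL19 at 3.65 (camera adjusted p = 3.89e-05; adjusted p = 0.155 with an estimated correlation). Of 96 cytochrome P450 genes, 50 rose and 13 fell (51 and 16 adjusted over the list alone), with MpCYP829-like43 at 9.70 and MpCYP822-like6 at 3.28 (camera adjusted p = 2.05e-04; adjusted p = 0.155 with an estimated correlation). Cupin and germin-like genes rose in 26 of 45 cases and fell in 8, the same numbers adjusted over the list alone, with MpPR15d at 8.05 and MpPR15h at 6.25 (camera adjusted p = 4.88e-04; adjusted p = 0.456 with an estimated correlation). Of 30 dioxygenase genes, 14 rose and 4 fell, the same numbers adjusted over the list alone, with MpDOXC8 at 6.28 and MpDOXC12 at 4.58 (camera adjusted p = 0.0387; adjusted p = 0.505 with an estimated correlation). The call for 2-oxoglutarate dioxygenases was lost without Mpez1-1 replicate 2 and without Mpez1-1 replicate 3.

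The other lists did not stand apart from the remaining genes in set 1 by camera; where adjustment over the list alone gave other numbers, these are added. Among transcription factor genes, 12 of 50 MYB genes rose and 16 fell (12 and 17 over the list alone; adjusted p = 0.715), 11 of 40 bHLH genes rose and 11 fell (0.981), and 3 of 17 homeobox genes rose and 5 fell (3 and 7 over the list alone, 0.815). In the homeobox list MpBELL1, of the family of KNOX partners, rose by 3.39 and MpC2HDZ fell by 1.12 on the log2 scale. AP2/ERF and WRKY genes rose in 15 of 32 cases and fell in 3 (16 and 3 over the list alone, adjusted p = 0.0537), with MpERF12 at 5.02 and MpWRKY3 at 4.88. Of 9 PRC2 and Polycomb genes, 3 rose and 2 fell (adjusted p = 0.589). Histone genes rose in 4 of 27 cases and fell in 2 (0.905), with MpH2A.W.1, of the heterochromatin-associated histone family, rising at least 19.5-fold from 0 counts. Among histone-modifying enzymes 9 of 53 rose and 12 fell (9 and 8 over the list alone, 0.715), with MpATXR3 at 3.79 and MpATXR5, of a family of H3K27 monomethyltransferases, at 3.75. DNA methylation and small RNA genes rose in 5 of 22 cases and none fell by edgeR (0.407), including MpPIWIb, of the Argonaute superfamily, at 5.55, and MpNRPD1, named for the largest subunit of RNA polymerase IV, from 17.0 to 36.5 CPM. Of 82 class III peroxidase genes, 25 rose and 28 fell (26 and 28 over the list alone, 0.715), and of 39 polyphenol oxidase genes 18 rose and 11 fell (0.478). Counts that rose and fell were 51 and 34 of 130 cell wall enzyme genes (53 and 36 over the list alone, 0.478), 13 and 6 of 30 glutathione S-transferase genes (0.143), 7 and 2 of 14 lipoxygenase genes (0.222), 32 and 17 of 84 ABC transporter genes (0.222) and 17 and 20 of 71 receptor-like kinase genes (0.478). Of the 28 auxin pathway genes 7 rose and 5 fell (0.752), with the auxin efflux carrier genes MpPIN3 at 1.78 and MpPIN4 at 3.54. Of 31 cell cycle genes 2 rose and 3 fell (0 and 0 over the list alone, 0.715), and 2 of 5 heat shock genes rose (0.589). Lists for other tissues were 9 risen and 2 fallen of 20 acyl-CoA synthetase and reductase genes of sporopollenin type (0.204), 3 and 1 of 7 germ cell genes (0.278) and 3 and 0 of 13 V chromosome genes (2 and 0 over the list alone, 0.478). In the germ cell list MpBNB (MpBHLH20), which specifies gametangium initials, rose at least 20.8-fold from 0 counts, the sperm fusion gene MpGCS1 rose by 1.32 and MpRKD fell by 0.46. Of 2 MADS-box genes, MpMADS1 rose by 0.51, and both passed adjusted over the list alone; the list was too short to test by camera.

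In set 2, the Mpknox2-1 Mpez1-2 thalli showed rises of many of the same genes against their own controls. MpR2R3-MYB19 went from 0 counts to 55.4 ± 2.89 CPM, at least 561-fold higher, and MpPR1g from 0 counts to 41.1 ± 4.35 CPM, at least 418-fold. MpPYL2 and MpBZR3 rose from 0 counts at least 592-fold and 428-fold. MpDIR47 went from 8.55 ± 1.66 to 635 ± 78.2 CPM (log2 fold change 6.21, SE 0.15, edgeR adjusted p = 5.25e-08). MpUGT19 fell from 8.47 ± 1.21 to 1.98 ± 0.529 CPM (log2 fold change -2.10, SE 0.25, edgeR adjusted p = 1.52e-05).

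Also risen from 0 counts in set 2 were MpCYP716-like24 (at least 131-fold), MpPR15f (at least 80.0-fold), MpBHLH25 (at least 54.4-fold), Mp3R-MYB6 (at least 68.5-fold), MpTPS6 (at least 86.2-fold) and MpRING1B3 (at least 34.8-fold). MpGDPD fell from 218 ± 31.3 to 57.5 ± 17.3 CPM, and MpHCT from 275 ± 44.5 to 118 ± 17.9 CPM. On the log2 scale MpPOD4 changed by -1.54, MpPPO6 by -1.53, MpPOD25 by -1.24, MpPOD94 by -1.09, MpCE8.14 by -1.15 and MpCYP814-like by -0.98.

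Of 12744 genes tested in set 2, 4815 passed at an edgeR adjusted p under 0.05, of which 2602 rose and 2213 fell; 1337 rose and 111 fell by at least 1 log2 unit. Of genes with 0 counts in all 3 controls, 102 had at least 10 counts in each Mpez1-2 library, and 0 genes met the reverse condition. On simulated counts with the means of this set a mean of 6.73% of calls were false, again above the nominal 5%.

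In set 2, 9 lists rose by camera with the preset correlation. Dirigent genes rose in 34 of 52 cases and fell in 1 (35 and 1 adjusted over the list alone), with MpDIR45 at 6.08 and MpDIR64 at 5.39 (camera adjusted p = 1.00e-08; adjusted p = 0.162 with an estimated correlation). Of 57 cupin and germin-like genes, 30 rose and 5 fell (32 and 5 adjusted over the list alone), with MpPR15d at 6.10 and MpPR15h at 3.73 (camera adjusted p = 6.23e-06; adjusted p = 0.0906 with an estimated correlation). Polyphenol oxidase genes, which oxidise phenols, rose in 23 of 41 cases and fell in 4, the same numbers adjusted over the list alone, with MpPPO15 at 5.38 and MpPPO34 at 4.30 (camera adjusted p = 2.01e-04; adjusted p = 0.274 with an estimated correlation). Class III peroxidase genes rose in 56 of 120 cases and fell in 14 (56 and 15 adjusted over the list alone), with MpPOD160 at 3.66 and MpPOD168 at 2.71 (camera adjusted p = 0.00131; adjusted p = 0.478 with an estimated correlation). Of 18 terpene synthase genes, 11 rose and 1 fell, the same numbers adjusted over the list alone, with MpMTPSL19 at 2.31 and MpFTPSL3 at 1.99 (camera adjusted p = 2.98e-04; adjusted p = 0.162 with an estimated correlation). Cytochrome P450 genes rose in 48 of 92 cases and fell in 13 (48 and 17 adjusted over the list alone), with MpCYP829-like43 at 7.29 and MpCYP822-like6 at 2.93 (camera adjusted p = 2.98e-04; adjusted p = 0.162 with an estimated correlation). Phenylpropanoid and flavonoid enzyme genes rose in 26 of 65 cases and fell in 7 (28 and 7 adjusted over the list alone), with MpDFR-like1 at 2.89 (camera adjusted p = 0.00230; adjusted p = 0.323 with an estimated correlation). In that list MpPKS/CHS4, named for the chalcone synthase family, rose at least 149-fold from 0 counts. Late embryogenesis abundant protein and oleosin genes rose in 23 of 50 cases and fell in 5 (23 and 7 adjusted over the list alone), with MpDHN2 at 0.95 (camera adjusted p = 0.00492; adjusted p = 0.274 with an estimated correlation). Of 33 AP2/ERF and WRKY genes, 15 rose and 3 fell (15 and 4 adjusted over the list alone), with MpERF12 at 5.59 and MpWRKY3 at 3.62 (camera adjusted p = 0.0128; adjusted p = 0.274 with an estimated correlation).

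The lists without a camera call in set 2 are given in the same way. Of 49 MYB genes 12 rose and 2 fell (11 and 2 over the list alone; adjusted p = 0.229), of 38 bHLH genes 14 rose and 3 fell (15 and 4 over the list alone, 0.109), and of 17 homeobox genes 4 rose and 4 fell (5 and 4 over the list alone, 0.686). MpBHLH37 rose by 5.93 and MpBELL1 by 5.13, while MpC2HDZ fell by 0.50 on the log2 scale. PRC2 and Polycomb genes rose in 4 of 10 cases and fell in 1 (0.109). Histone genes rose in 8 of 27 cases and fell in 4 (0.987), and MpH2A.W.1 rose at least 16.5-fold from 0 counts. Of 53 histone-modifying enzyme genes 5 rose and 8 fell (4 and 7 over the list alone, 0.686), with the acetyltransferase gene MpHAT10 at 6.10, MpATXR5 at 4.84 and MpATXR3 at 3.20. DNA methylation and small RNA genes rose in 4 of 20 cases and fell in 3 (4 and 5 over the list alone, 0.686). In that list MpNRPE1b, named for the largest subunit of RNA polymerase V, rose by 3.30, and MpPIWIb, with 2 counts in the controls and 6 in the Mpez1-2 libraries, was too low to test. Dioxygenase genes rose in 11 of 29 cases and fell in 5 (0.169), with MpDOXC8 at 5.53. Risen and fallen members numbered 44 and 40 of 144 cell wall enzyme genes (45 and 43 over the list alone, 0.987), 10 and 9 of 30 glutathione S-transferase genes (0.686), 7 and 2 of 15 lipoxygenase genes (8 and 2 over the list alone, 0.0683), 26 and 12 of 86 ABC transporter genes (27 and 14 over the list alone, 0.277) and 20 and 12 of 69 receptor-like kinase genes (20 and 13 over the list alone, 0.987). Auxin pathway genes rose in 8 of 27 cases and none fell by edgeR (0.109), with MpPIN3 at 3.14 and MpPIN4 at 1.41. Of 31 cell cycle genes 2 rose and 6 fell (1 and 4 over the list alone, 0.0883), with the cyclin-dependent kinase gene MpCDKA at -0.36. None of 6 heat shock genes passed by edgeR (0.686). Acyl-CoA synthetase and reductase genes of sporopollenin type rose in 5 of 19 cases and fell in 1 (4 and 1 over the list alone, 0.634), germ cell genes in 1 and 1 of 6 cases (0.987), and V chromosome genes in 2 and 0 of 10 cases (0.686). Neither of the 2 MADS-box genes passed, MpMADS1 having a log2 fold change of 0.19.

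**Figure D2:**
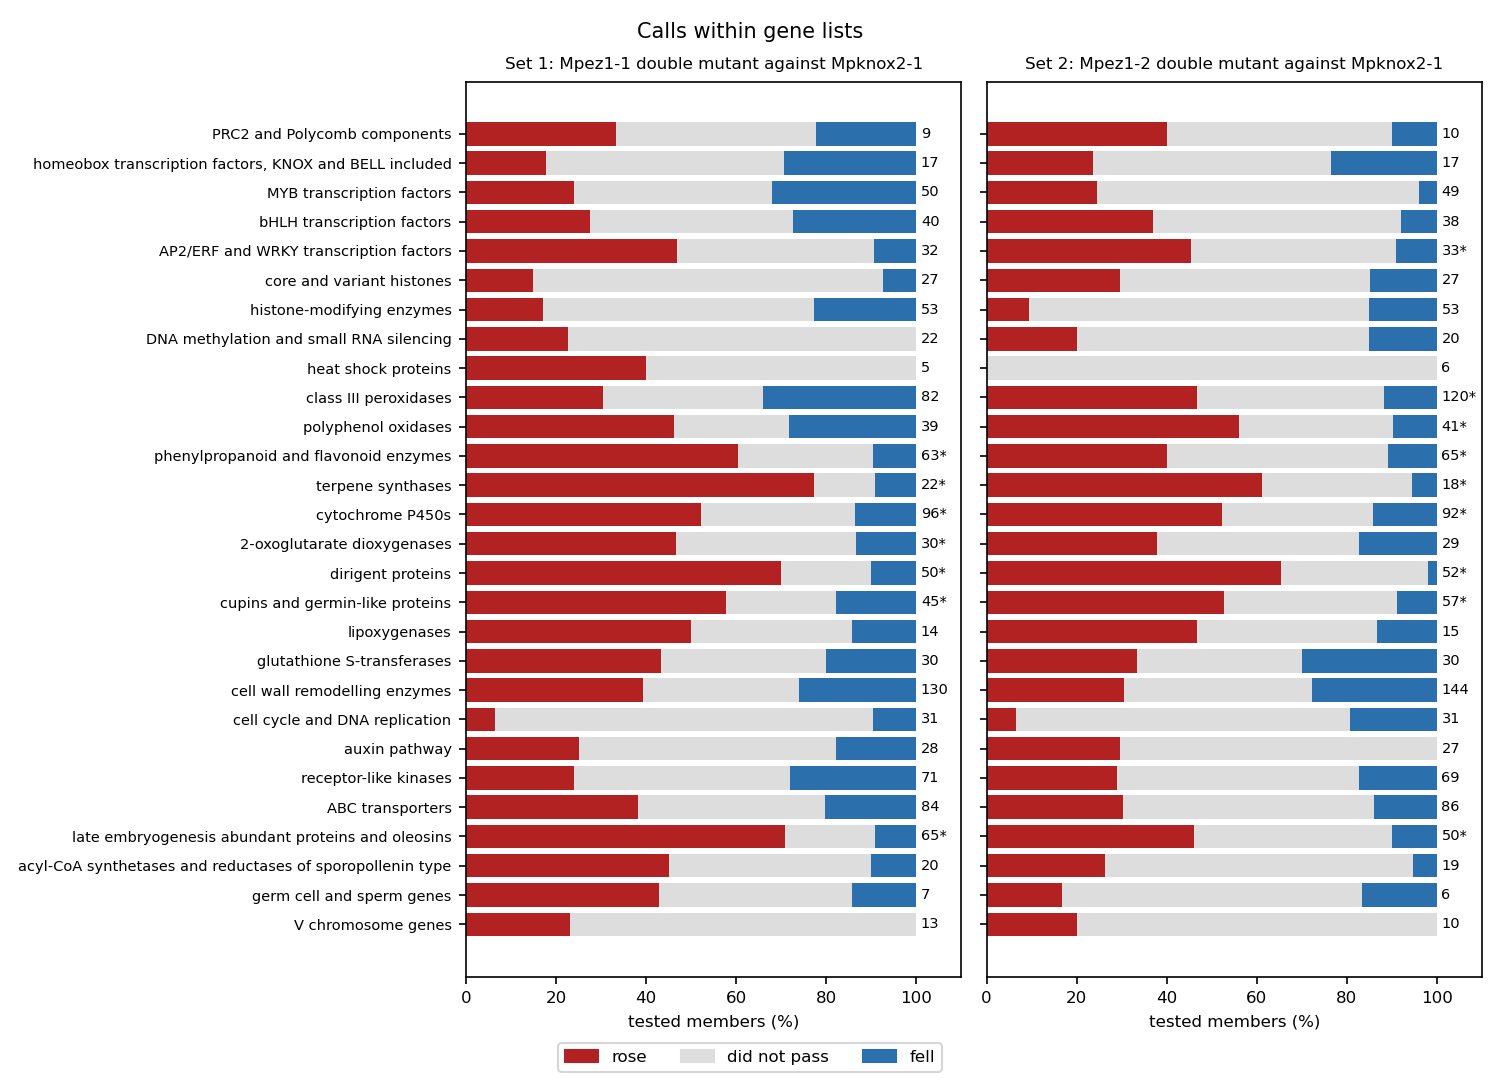
Percent of tested members of each gene list that rose, fell or did not pass at an edgeR adjusted p under 0.05, in set 1 (left) and set 2 (right); numbers beside the bars are tested members and a star marks a camera adjusted p under 0.05 with the preset correlation. Dirigent genes rose in 35 of 50 cases in set 1 and 34 of 52 in set 2; with an estimated correlation 0 lists passed in either set.

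Across both sets, 1650 genes rose in both and 1358 fell in both, of 12261 tested in both; 620 and 540 were the numbers for independent lists of these sizes. Opposite calls were made for 222 genes, against 1158 for independent lists. The controls of the sets were separate libraries. Log2 fold changes of the sets correlated across genes, which are not independent replicates, with Pearson's r of 0.83 and Spearman's rho of 0.60. Of the genes risen in both, 72.4% had the larger rise in set 1 (70% to 74% with each library left out), and of those fallen in both 91.9% had the larger fall there (88.9% to 92.8%). On average over the sets 3629 genes rose and 3934 fell of 13244 tested. The balance turned with DESeq2 (3694 rose and 3585 fell), with RLE scaling (3765 and 3705) and at 1 log2 unit or more (1798 and 286). Among genes with 0 counts in all 6 control libraries, 51 had at least 10 counts in each of the 6 double mutant libraries, 17 of them with a symbol, such as MpR2R3-MYB19, MpPR1g and MpCYP716-like24.

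Symbol families with at least 10 tested members were compared with the 2422 tested genes that had a symbol, of which 19.4% rose in both sets. Pathogenesis-related (PR) genes, typical of defence responses, rose in both sets in 25 of 27 cases, dirigent genes in 29 of 50 and cytochrome P450 genes in 41 of 90 (one-sided Fisher's exact tests, Benjamini-Hochberg adjusted p = 1.15e-14, 3.11e-08 and 1.33e-07 over 55 families). These tests treat genes as independent and were made after the calls were known. Genes silent in the controls, such as MpPR1g and MpPR15f, enter only through high counts in the double mutants, which favours rises. PR genes as a family were not among the lists tested by camera. As lists, dirigent and cytochrome P450 genes had no camera call with an estimated correlation (adjusted p = 0.155 for each in set 1 and 0.162 for each in set 2). No other family passed for rises; the next, late embryogenesis abundant protein genes, rose in both sets in 15 of 41 cases (adjusted p = 0.0943). For falls in both sets the only group to pass was that of symbols beginning with MpC and a digit, which mixes homeodomain genes such as MpC2HDZ and MpC4HDZ with enzyme genes such as MpC4H3, with 6 of 10 (adjusted p = 0.00803). Members of these families can lie side by side as similar copies, and how reads shared between copies were counted is not given in the sources used here.

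**Figure D3:**
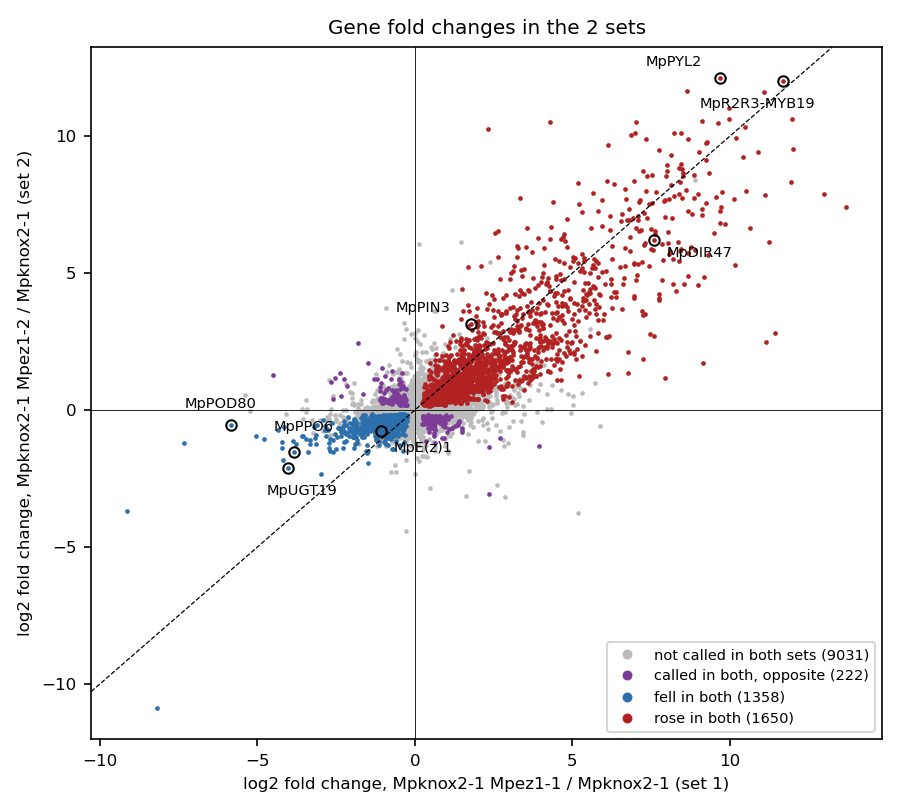
Log2 fold change of each gene tested in both sets, set 1 on the horizontal and set 2 on the vertical axis, coloured by its calls; the dashed line marks equal change and fitted values of genes with 0 control counts depend on the prior count. There were 1650 genes that rose in both sets, 1358 that fell in both and 222 called in opposite directions.

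The sets also differed in the size of change, which was tested as the set 2 change minus the set 1 change. MpPOD80 (Mp5g06870), a peroxidase gene, went from 181 counts to 2 in set 1, a pooled ratio of 0.0150 with an interval of 0.00180 to 0.0550, and from 26.0 ± 3.53 to 17.8 ± 0.273 CPM in set 2 (difference 5.28, edgeR adjusted p = 3.16e-05). The glucanase-type gene MpGH17.15 (Mp6g00360) did not pass in set 1, at 491 ± 42.5 and 607 ± 53.4 CPM, and fell in set 2 from 130 ± 16.0 to 57.8 ± 0.618 CPM (difference -1.52, adjusted p = 5.36e-05). MpPEX11b (Mp1g26710), named for a peroxisome division factor, fell in set 1 from 290 ± 13.9 to 149 ± 9.94 CPM and did not pass in set 2, at 207 ± 7.53 and 230 ± 7.57 CPM (difference 1.07, adjusted p = 7.13e-05). MpCYP829-like16 (Mp2g20490), a cytochrome P450 gene, rose in both, by 4.43 in set 1 and 1.66 in set 2 (difference -2.82, adjusted p = 7.13e-05).

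The difference passed for 3050 of 13244 genes, with a higher value in set 2 for 1419 and a lower value for 1631. These calls rest on a single dispersion per gene for both sets, while replicate noise was mostly larger in set 1. Among the auxin carriers MpPIN3 rose more in set 2 (difference 1.32, adjusted p = 4.76e-04) and MpPIN4 rose more in set 1 (difference -2.17, adjusted p = 5.94e-04). MpHSP90-1, a heat shock protein gene, rose by 0.86 in set 1 and had a value of 0.02 in set 2 (difference -0.88, adjusted p = 0.00221). Each allele was measured in 1 set only, so allele and set cannot be told apart. The split turned without set 1 control replicate 1 (1851 genes higher and 1095 lower in set 2), without set 1 control replicate 3 (1807 and 1195), without Mpez1-1 replicate 1 (2332 and 1509), and without Mpez1-1 replicate 1 and set 1 control replicate 2 together (1942 and 1244). In each of these settings the median difference of all genes was 0.0931 to 0.0973, against 0.00133 with all libraries. It was -0.00347 to 0.0112 with any other single library left out. The turn thus went with a shift of all genes.

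Counts at TE copies rose far more often than they fell in both sets. The places of copies relative to genes were not used. Reads of a gene that holds or adjoins a copy were thus not separated from transcripts of the copy itself. Copy TE_homo_57228, of the Copia class of LTR retrotransposons, went from 0 counts to 27.8 ± 1.04 CPM in set 1 and to 129 ± 2.64 CPM in set 2, at least 308-fold and 1306-fold higher. TE_homo_15628, of a family with no assigned class, rose at least 311-fold and 220-fold from 0 counts, and TE_homo_57245, a DTC DNA transposon copy, at least 55.7-fold and 67.8-fold. Copies TE_homo_34931 and TE_homo_25305 fell, with log2 fold changes of -1.66 and -0.86 in set 1 and -1.17 and -0.69 in set 2; the set 2 call for TE_homo_34931 was lost without control replicate 1 (-0.99) and without Mpez1-2 replicate 2 (-0.88).

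Summed over copies, the family TE_00000121 rose from 4.66 ± 1.27 to 54.5 ± 5.73 CPM in set 1 and from 3.20 ± 1.05 to 34.8 ± 2.00 CPM in set 2. TE_00000072 rose by 5.26 and 3.07, TE_00000193 by 4.93 and 3.63 and TE_00000243 by 3.03 and 1.81 on the log2 scale, all of unassigned class. The Gypsy retrotransposon family TE_00000762 rose by 1.59 and 1.98. The only family that fell in both sets by edgeR was TE_00000309, at -1.70 and -0.65; its set 2 call was lost without control replicate 1 (-0.45), Mpez1-2 replicate 1 (-0.50) or Mpez1-2 replicate 3 (-0.56) and with the replicate number as a block (-0.65). Of families tested, 82 rose and 5 fell of 209 in set 1 (9 without Mpez1-1 replicate 1), and 83 rose and 6 fell of 161 in set 2 (2 without control replicate 1, Mpez1-2 replicate 1 or Mpez1-2 replicate 3); 57 rose in both.

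Of 318 TE copies tested in set 1, 171 rose and 20 fell, and of 315 in set 2, 149 rose and 9 fell (5 without control replicate 1, 16 without control replicate 3); 87 rose in both, where independent lists would share 59.6. By superfamily, 35 of 54 DTM DNA transposon copies rose in set 1 and 24 of 48 in set 2, and 28 of 65 and 17 of 47 Gypsy copies. All tested TE copies as a list rose against the genes (camera adjusted p = 1.57e-11 in set 1 and 2.06e-11 in set 2; with an estimated correlation adjusted p = 0.00459 and 0.00158). The lists of DTM copies kept their call with an estimated correlation in both sets (adjusted p = 0.0305 and 0.00766), as did copies of unassigned class (0.00611 and 0.00558). Copies of the Gypsy list had camera adjusted p = 1.31e-04 and 0.00127, with adjusted p = 0.0943 in set 1 and 0.0308 in set 2 with an estimated correlation. The Copia list, of 9 and 7 copies, had camera adjusted p = 0.0401 and 1.91e-04, with adjusted p = 0.101 and 0.0436 with an estimated correlation. For DTC copies these were 0.00194 and 0.0181 by camera, and adjusted p = 0.0436 and 0.0780 with an estimated correlation. The 5 DTA copies of set 1 had camera adjusted p = 4.37e-04 and adjusted p = 0.0421 with an estimated correlation. LTR copies of unknown superfamily had 0.00416 and 0.180 by camera, and adjusted p = 0.101 and 0.359 with an estimated correlation.

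On average over sets 234 TE copies rose and 20 fell of 466, and the difference between sets passed for 14 copies (38 with DESeq2). That count was 7 without set 1 control replicate 3, 8 without Mpez1-1 replicate 2 or Mpez1-2 replicate 2, 9 without Mpez1-2 replicate 1 and 22 without set 2 control replicate 2. Summed TE counts of the first tables without the Gypsy family TE_00000630 were 1588 ± 102 CPM in the set 1 controls and 3145 ± 185 CPM in the Mpez1-1 libraries, a ratio of 1.98. In set 2 they were 1649 ± 110 and 3700 ± 163 CPM, a ratio of 2.24 (exact two-sided permutation p = 0.1 in each set, the smallest that 3 against 3 allows). With that family, which took 28.2% to 78.3% of these TE counts, the ratios were 1.51 (exact permutation p = 0.3) and 1.65 (exact permutation p = 0.1). TE counts of the second tables, not scaled to library size, averaged 732606 ± 297465 in the set 1 controls and 660814 ± 140222 in the Mpez1-1 libraries. In set 2 they averaged 427770 ± 27844 and 408307 ± 53114, while gene counts were lower in the double mutants of both sets. Their sum was not tested, so the ratios above do not describe all TE counts. Only 19.3% of the 89262 annotated copies had a count in any library, and reads of near-identical copies cannot be placed with certainty, so single copies are less certain than family sums.

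**Figure D4:**
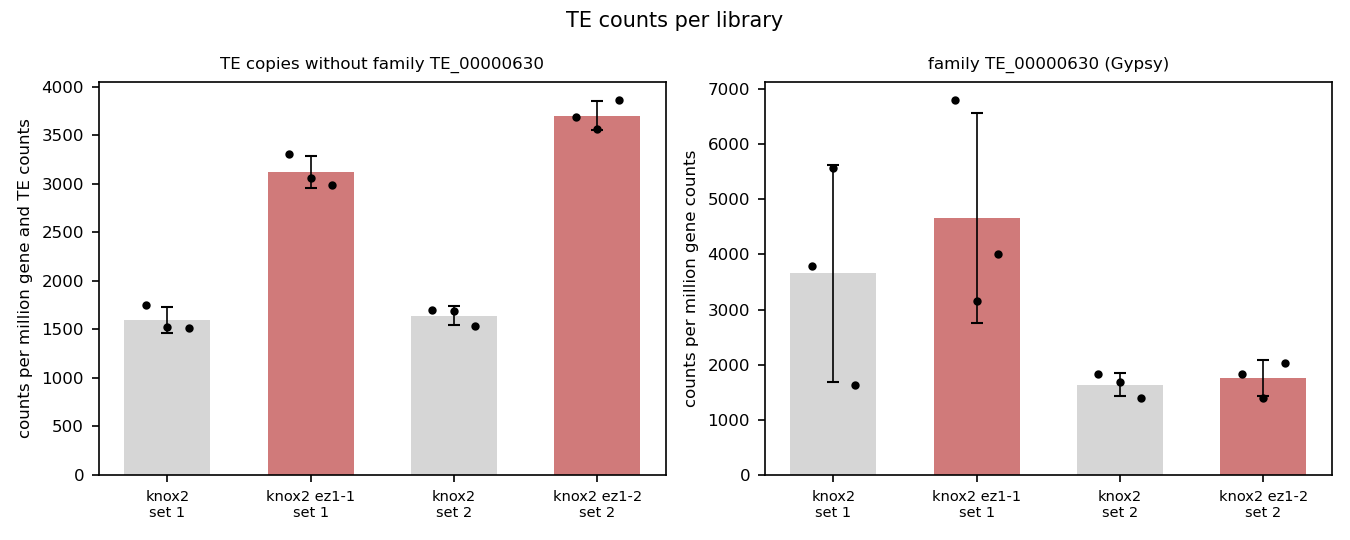
TE counts of the first tables per library, without the family TE_00000630 (left, CPM) and of that family alone (right, CPM). Bars are means of 3 libraries, error bars SD and points single libraries. Without the family the controls lie between 1510 and 1755 and the double mutants between 2991 and 3860, while the family itself ranged from 1403 to 6797 over the libraries with no separation of the groups in either set.

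Counts on the opposite strand of genes changed for fewer genes. Antisense counts of the cupin gene MpCupin53 (Mp3g12360) rose at least 42.1-fold and 19.5-fold, with sense log2 fold changes of 4.18 and 1.87. At Mp8g04880 antisense counts went from 1 to 134 in set 1, a pooled ratio of 182 with an interval of 32.1 to 7242, and rose at least 42.5-fold from 0 in set 2, where the sense strand had 0 counts in set 1 and 3 in the set 2 double mutants. Antisense counts of Mp5g21660 rose from 0, at least 23.5-fold in set 1 and 38.7-fold in set 2, beside sense rises of 7.28 and 6.02 on the log2 scale. They were 0.216% and 0.184% of its sense counts in the double mutants, below the median antisense share of abundant genes (0.464% and 0.374%).

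Of 1825 genes tested for antisense counts in set 1, 253 rose and 94 fell, and of 1549 in set 2, 151 rose and 60 fell. Scaled by the antisense tables' own totals, 200 rose and 119 fell in set 1 and 128 rose and 120 fell in set 2; this scaling moved the median log2 fold change of all antisense genes from 0.12 to -0.02 and from -0.05 to -0.21. The number of falls moved from 94 to 52 in set 1 with the replicate number as a block, from 60 to 37 in set 2 with DESeq2, and when single libraries were left out. In set 1 they numbered 48, 40 and 45 without control replicates 1, 2 and 3 and 37 without Mpez1-1 replicate 2. In set 2 they numbered 39 and 29 without control replicates 1 and 2, and 15, 24 and 26 without Mpez1-2 replicates 1, 2 and 3. With no filter 383 genes rose in set 1, without control replicate 2 and Mpez1-1 replicate 1 together 152 rose and 47 fell, and at 1 log2 unit or more 28 fell in set 2. All calls together were 210 without Mpez1-1 replicate 2, 212 without set 1 control replicate 2, and 133 and 136 without Mpez1-2 replicates 1 and 2. Counts of TE copies in the second tables are called antisense for short, although the strand taken for TE copies is not given. They rose in 483 and fell in 132 of 1168 cases in set 1, and rose in 502 and fell in 50 of 1204 in set 2. With the antisense tables' own scaling 409 rose and 155 fell in set 1, and 454 rose and 91 fell in set 2. Of these, DTM DNA transposon copies rose in 83 of 145 cases in set 1 and 75 of 140 in set 2.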

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

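The tests on the origin of the smaller rise in set 2 and the counts over other splits of the libraries were chosen after the results were seen; the test of each difference between sets was fixed beforehand.

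The response to the double mutation differed between sets for 3050 genes and 14 TE copies by the edgeR test of the difference, set 2 minus set 1. The named genes with the smallest adjusted p were MpPOD80 at 5.28, MpGH17.15 at -1.52, MpPEX11b at 1.07 and MpCYP829-like16 at -2.82 on the log2 scale. Among 100 splits of the libraries within the sets, 5 gave at least as many genes as the real 3050, the real one included, and the highest other gave 4634. For TE copies 6 of 100 splits gave at least 14, with a highest other of 70; that count was 7 without set 1 control replicate 3, 8 without Mpez1-1 replicate 2 or Mpez1-2 replicate 2, 9 without Mpez1-2 replicate 1 and 22 without set 2 control replicate 2. This comparison does not decide on chance, since the 4 other gene splits and the 5 other TE splits all kept the real groups of 1 set and so contain the response of that set, while the 81 splits with mixed groups in both sets gave at most 0 genes and 0 TE copies.

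Lists also differed between sets by camera with the preset correlation. Changes were higher in set 2 for MYB (adjusted p = 0.0479), bHLH (0.0268), class III peroxidase (2.67e-06) and polyphenol oxidase genes (0.0277). They were lower in set 2 for terpene synthase (0.0407), glutathione S-transferase (0.0131) and late embryogenesis abundant protein and oleosin genes (2.54e-06). With an estimated correlation the adjusted p of these 7 lists lay between 0.401 and 0.450. In the peroxidase list 40 members were higher in set 2 and 7 lower by the gene-level test, and in the late embryogenesis abundant list 4 were higher and 11 lower.

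Genes that rose on average over sets rose less in set 2: the median difference of their log2 fold changes was -0.42 (-0.46 to -0.36 with each library left out), and 74.5% of 3629 had the smaller value there (72.7% to 75.2%). A higher level in the set 2 controls as the whole origin is argued against, since the double mutant levels were lower in set 2 by a median of -0.53, while control levels differed by -0.09. A uniform dilution of the set 2 double mutant RNA by RNA of control level is argued against as the whole origin: adjusted over these genes, 157 had a larger rise in set 2 and 1149 a smaller one, and the larger ones were 12.02% of these calls (11.5% to 16.8% with each library left out), above the 5% of false calls allowed. Such a dilution beside differences of single genes stays open, and a first test, which asked for larger rises in over 5% of the 3629 genes, found 138 and did not go against dilution. The allele and the experimental set cannot be told apart, since each allele was measured in 1 set, and a difference between the alleles stays open as an untested biological explanation.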

How the results depend on the processing

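The fits without MpVg01240 and 3 abundant TE families and those without the 2 set 1 libraries with the most MpVg01240 counts were chosen after the data were seen.

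Counts of genes, TE copies, TE families and antisense features stayed within 1.5 times their value under the settings tried, except those given here; the cause was not tested unless stated. Requiring 1 log2 unit, which by construction keeps fewer genes, left 2626 genes in set 1, 1448 in set 2, 2084 for the mean, 1147 for the difference and 1005 in both sets. With no filter, which tests more copies, 316 TE copies passed in set 1, 261 in set 2 and 26 for the difference. For that difference DESeq2 gave 38. Without the 2 set 1 libraries the difference had 22 TE copies and set 1 had 199 antisense genes.

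With each library left out in turn, TE copies of the difference ranged from 7 to 22: 7 without set 1 control replicate 3, 8 without Mpez1-1 replicate 2 or Mpez1-2 replicate 2, 9 without Mpez1-2 replicate 1 and 22 without set 2 control replicate 2. Antisense genes ranged from 210 to 441 in set 1 and from 133 to 254 in set 2. Those below the limit were 210 without Mpez1-1 replicate 2, 212 without set 1 control replicate 2, 133 without Mpez1-2 replicate 1 and 136 without Mpez1-2 replicate 2.

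Of gene lists, 7 passed in set 1 and 9 in set 2 by camera; with an estimated correlation 0 passed in either, and by fry, which tests each list by itself, 22 and 25 passed. Fry gave the opposite direction to camera, which had no call there, for MYB genes in set 1 (adjusted p = 3.8e-06), histone genes in set 2 (0.0164) and histone-modifying enzyme genes in set 2 (0.00315).

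Whether the replicate numbers pair the libraries stays open. Same-number correlations of deviations were low, at -0.00346 to 0.0968. Yet 9 of 12 libraries, among them every library of set 2, correlated best with their own number, a hint of pairing from the data. With the replicate block 6444 genes passed in set 1, 4935 in set 2, 7551 for the mean and 3078 for the difference, and 243 and 170 antisense genes.

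Of 2795 fold changes of named genes, 2744 kept direction and call, 24 lost the call, 15 gained one, 12 uncalled values near 0 changed sign and 0 calls reversed in sign by edgeR or DESeq2. At these depths genes near the floor cannot show moderate changes.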

Other observations

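The test that neighbouring genes rose together and the test of genes next to antisense rises were written before their results; the tests on abundant features, on wrong-strand reads and on other splits of the libraries were chosen after the results were seen.

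Genes that rose by over 1 log2 unit in both sets lay next to each other more often than by chance. Of 12085 genes tested in both sets and placed in the reference order, 938 rose this way, and they formed 301 adjacent pairs, against a mean of 72.6 and a maximum of 103 over 10000 permutations. Without pairs whose symbols belong to 1 family there were 265 pairs, against a mean of 71.5 and a maximum of 101 (permutation p = 0.0001, the smallest these permutations can give). The longest run held 10 genes, from Mp3g09150 to Mp3g09250, with the immune receptor-type genes MpNBS-LRR5 and MpNBS-LRR6 and the transporter gene MpNPF9. A run of 7 genes held MpPYL2 beside 4 cytochrome P450 genes, MpCYP829-like7 to MpCYP829-like10, and another run of 7 held the terpene synthase gene MpMTPSL2 beside MpCPT5. Regional loss of repression in the double mutants is a candidate explanation that was not tested, since the 265 pairs are the pattern it would explain. Unnamed tandem copies were not excluded.

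Of 253 genes whose antisense counts rose in set 1, 150 had no called rise on the sense strand, and of 151 in set 2, 101 had none. Sense counts fell by edgeR for 8 and 5 of these, and for 142 and 96 they were not called or were too low to test. For most of the 150 and 101 genes, sense reads counted on the wrong strand are argued against. Of them, 144 and 100 had antisense counts above 10 times the median antisense share of abundant genes (0.464% and 0.374% of sense counts). Among genes whose sense counts also rose, that origin is argued against for 52 of 103 in set 1 and 34 of 50 in set 2, which lay above that bound, and stays open for the 51 and 16 within it, Mp5g21660 among them in both sets. Reads of an adjacent gene may contribute. In set 1 an adjacent gene had risen beside 64.0% of the antisense genes without a called sense rise and beside 29.1% of the others (odds ratio 4.33, two-sided Fisher's exact p = 2.52e-15). In set 2 these shares were 57.3% and 19.8% (odds ratio 5.41, two-sided Fisher's exact p = 2.18e-14). Risen genes cluster and the reference gives no strand, so read-through from a neighbour and a shared regional rise were not separated.

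MpVg01240, of the V chromosome, the Gypsy family TE_00000630 and the antisense counts of families TE_00000015 and TE_00000002 varied together between libraries, with MpVg01240 between 2447 and 14456 CPM. Over 12 libraries Pearson's r with MpVg01240 was 0.972, 0.960 and 0.935 and Spearman's rho 0.874, 0.930 and 0.832 (permutation p for r = 1e-05, 1e-05 and 3e-05, adjusted over 3 relations 1.5e-05, 1.5e-05 and 3e-05, and for rho = 0.00048, 7e-05 and 0.00153). Those permutations crossed the 2 sets, and MpVg01240 was higher on average in set 1, so a difference between sets enters these p. Permuted within a set, the exact permutation p for r was 0.00972, 0.0194 and 0.0208 in set 1 and 0.0222, 0.0278 and 0.0389 in set 2. The features were chosen after their values were seen, which none of these p takes into account. Without the 2 most extreme libraries r was 0.962, 0.961 and 0.932, and the lowest r within a set was 0.834. One abundant RNA source carried over in varying amounts stays open as a candidate explanation, and the r of 0.834 does not decide, since any shared origin gives it. The Mpez1 genotype as the whole origin is argued against: ranked on set 1 alone by deviations from the group means, the families had rank 1 of 23 for TE_00000630 and ranks 1 and 3 of 57 for the antisense ones, and in set 2 such deviations had r of 0.985, 0.993 and 0.990 with those of MpVg01240 (exact permutation p = 0.0278 for each, the smallest possible, and 0.0417 adjusted over the 6 families of ranks 1 to 3). Of the other 3 so ranked, antisense TE_00000094 had r of 0.989 in set 2 (adjusted p = 0.0417), while TE_00000147 (r 0.715) and TE_00000758 (r -0.663) did not pass (adjusted p = 0.333 for each). The bound at rank 3 was set after the results were seen. The families of rank 4, TE_00001068 and antisense TE_00000346, had exact permutation p of 0.694 and 0.472 in set 2, so a wider bound raises the adjusted p. The features were first picked over all 12 libraries, so set 2 was not fully held out. The argument thus rests on the ranks and r more than on the adjusted p.

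Within each set the 10 splits of 6 libraries are too few for a share under 0.05. The real split was the 1 split with any call by edgeR: 6395 genes, 191 TE copies, 87 TE families, 347 antisense genes and 615 antisense TE copies in set 1, and 4815, 158, 89, 211 and 552 in set 2, with 0 as the highest of the others. For the mean over sets, 1 of 100 splits reached the real 7563 genes, the real one itself, with 4666 as the highest other, and 1 of 100 reached 254 TE copies, with 70 as the highest other. That share lies under 0.05, which argues against chance for these counts without excluding it. The splits with 4666 genes and with 70 TE copies kept the real groups of set 1 and so contain the response of that set.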
